A study of Homo sapiens with 22 samples.

How the data were processed

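RNA sequencing was analysed in 22 libraries labelled as MDA-MB231, an established human triple-negative breast cancer line. They fall into 3 experiments. The first holds 2 control libraries (Ctrl) and 2 libraries of cells given Nexturastat A at 7.65 µM for 2 days. The second holds 3 libraries each of cells with a control hairpin (shCtrl) and with either of 2 hairpins against HDAC6 (shHDAC6-1 and shHDAC6-2), sampled at day 0. The last holds 3 libraries each of cells given DMSO, HPOB or Tubastatin A, sampled at day 2. The titles of the last group carry the letters TSA, which also abbreviate trichostatin A, but its treatment label reads Tubastatin A, and that label was used. The labels give DMSO as the treatment of the Ctrl group too. Doses of HPOB and Tubastatin A, and the times of those treatments beyond the sampling day, are not given in the sources used here.

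The deposited values are raw counts of reads per gene symbol, with 1 table per library and 26485 symbols in each. Per the labels, the authors trimmed reads with Trim Galore 0.6.7, aligned them with STAR 2.7.9a to GRCh38, counted them with featureCounts 2.0.3 and used DESeq2 1.30.1. The gene annotation and the strandedness of counting are not given in the sources used here. Of the symbols, 23925 were matched to GENCODE release 29, which supplied positions on GRCh38, the GC content and the length of the longest transcript. The symbols include none of the mitochondrially encoded genes. Counts per library ranged from 31.2 to 85.9 M (mega). Intervals for ratios of counts and the floor of 3 counts cover counting error alone, since reads without molecular identifiers are not independent molecules.

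Each experiment was fitted separately with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr by group (minimum count 10, minimum total 15), robust quasi-likelihood dispersion and the quasi-likelihood F test. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the genes tested are described as called. Log2 fold changes are given with the standard error (SE) or the 95% interval of the fit, and levels as library-scaled counts (CPM, as edgeR computes them) with the standard deviation (SD) of the libraries. These levels use the TMM factors of the fit they come from, so a library has slightly different values in different fits. The differences between the effect of Nexturastat A and that of the other compounds were tested as interaction terms in 1 fit of the first and last experiments, where each compound is set against the controls of its own experiment. Genes tested numbered 16678, 17653 and 15338 in the 3 experiments and 17083 in the joint fit. For a gene with no counts in the control libraries, the fold is a lower bound against a floor of 3 counts over the control group. For other genes with few counts in a group, the ratio of counts is given with its counting interval.

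The comparisons, the named genes and 35 gene lists were fixed before the data were examined, and 34 of the lists had measured members. Named genes are HDAC6, any other histone deacetylase or sirtuin that was called, the 8 highest and 8 lowest log2 fold changes of a comparison with a control (4 and 4 between compounds) among called genes with a mean log2 CPM of at least 2 and no overlap between the groups, and the list members with the largest changes. The 4 genes called with HPOB are followed through the other comparisons, a choice made after their values were seen. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. In sensitivity runs the members of a list were followed in the comparisons in which camera called it. Overlaps between sets of calls were set against the number given by independence and, where the comparisons share controls, against 20 simulations of unchanged groups.

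Alternatives fixed beforehand were DESeq2 1.42.0 (size factors, and its Wald test), no filter on low counts, a minimum mean CPM of 5, a replicate block, leaving out each library in turn, fits of 2 groups alone, the DMSO libraries as controls for Nexturastat A, a fold minimum of 1.5 for overlaps, and the estimated correlation for lists. Added after seeing the data were the knockdown comparisons within replicates 1 and 2, limma voom with library quality weights, removal of per-library trends on GC content and transcript length (splines with 3 degrees of freedom), and leaving out HPOB replicate 3 together with Tubastatin A replicate 2. In the knockdown experiment, residuals of libraries that share a replicate number correlated across genes at 0.270 to 0.975 over 9 pairs. These values cannot tell whether the numbers pair libraries. Replicate 3 stood apart in each group, which alone can give positive values, and pairs of unlike number were not compared. In the compound experiment the range was -0.260 to 0.461 over 9 pairs. Among the 20 pairs of replicates within a group, none repeated the same counts, as the lowest chi-square per degree of freedom was 4.42.

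The steps were tested on simulated data with 200 changed genes. In the design of the first experiment, 52.2% of genes changed 2-fold were recovered and 33 of 127 calls were false. The compound design recovered 74.6%, with 7 of 139 calls false, and replicates 1 and 2 of the knockdown design recovered 73.1%, with 12 of 157 false. The knockdown design with all 9 libraries recovered 0 of the changed genes, even at 4-fold. In the joint design, 32.8% were recovered at 2-fold and 7 of 76 calls were false.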

Results

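The data are gene-level read counts of 22 libraries labelled as MDA-MB231. Ctrl (n = 2) had 60.2 to 61.6 M counts per library (M, mega) and Nexturastat A (n = 2) had 58.0 to 59.4 M. In the knockdown experiment, shCtrl (n = 3) had 52.8 to 64.8 M, shHDAC6-1 (n = 3) had 50.9 to 85.9 M and shHDAC6-2 (n = 3) had 58.9 to 63.5 M. In the compound experiment, DMSO (n = 3) had 31.2 to 37.4 M, HPOB (n = 3) had 32.1 to 40.9 M and Tubastatin A (n = 3) had 36.9 to 41.3 M. The series concerns HDAC6, a mainly cytoplasmic deacetylase of tubulin and other proteins, whose gene lies on chromosome X from 48801377 to 48824982 (GRCh38).

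HDAC6 mRNA stood at 39.6 CPM ± 12.2 (SD, n = 3) in shCtrl, 11.5 CPM ± 0.321 (SD, n = 3) with shHDAC6-1 and 12.7 CPM ± 1.29 (SD, n = 3) with shHDAC6-2, which is 28.9% and 32.2% of the shCtrl mean. Set against the shCtrl library of the same number, the level was 27.5%, 22.3% and 43.8% with shHDAC6-1 and 26.7%, 25.7% and 53.5% with shHDAC6-2. HDAC6 mRNA was not called with any of the inhibitors of the enzyme. It stood at 26.6 CPM ± 0.445 (SD, n = 2) with Nexturastat A against 30.3 CPM ± 0.930 (SD, n = 2) in Ctrl, and at 96.1 CPM ± 29.6 (SD, n = 3) with HPOB and 104 CPM ± 15.3 (SD, n = 3) with Tubastatin A against 91.1 CPM ± 6.42 (SD, n = 3) in DMSO.

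**Figure D1:**
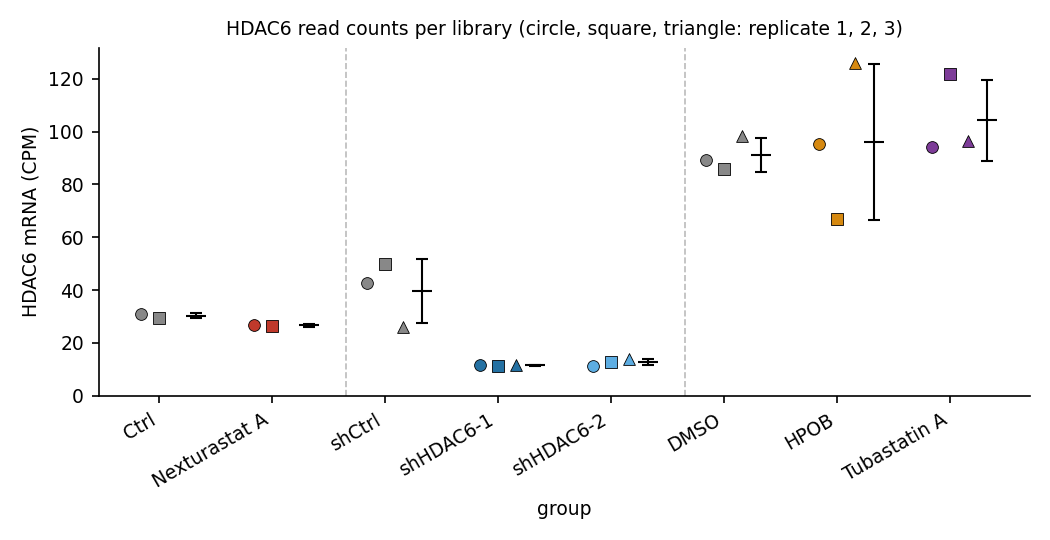
HDAC6 mRNA (vertical axis, CPM) in each library of the 8 groups (horizontal axis), with the mean and SD of the group beside the points and dashed lines between the 3 experiments. The hairpin groups lie from 11.1 CPM up, and all 6 of their libraries lie below the lowest shCtrl library at 26.1 CPM.

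Libraries differed by more than their groups. Across genes, which are not independent replicates, log2 CPM of replicates 1 and 2 of the knockdown experiment (6 libraries, shCtrl included) correlated at 0.961 to 0.995 with each other but at 0.689 to 0.708 with Ctrl. By contrast, shCtrl replicate 3 correlated with Ctrl at 0.953 to 0.965. CDKN2A, a cell cycle inhibitor whose gene MDA-MB231 cells have lost, stood at 132 to 175 CPM in those 6 libraries, 8.83 and 29.05 CPM in replicate 3 of the hairpins, 0 in shCtrl replicate 3 and at most 0.0320 CPM in the 13 libraries of the compounds and their controls. IRS4, an insulin receptor substrate, stood at 303 to 641 CPM in the 6 libraries, and the fetal RNA-binding protein gene IGF2BP1 at 254 to 376 CPM. Replicate 3 of both hairpins correlated at 0.701 to 0.705 with shCtrl replicate 3. DMSO correlated with Ctrl at 0.819 to 0.828, so the first and last experiments also stood apart. On a scaling of all libraries, CD74 stood at 0.0325 and 0.0644 CPM in Ctrl and 149 to 165 CPM in DMSO. MMP1 stood at 0.601 and 1.03 CPM in Ctrl and 199 to 207 CPM in DMSO. NKX2-1 went the other way, at 63.2 and 51.96 CPM in Ctrl and 0.788 to 1.55 CPM in DMSO. KRT8 was alike, at 697 and 750 CPM in Ctrl and 734 to 750 CPM in DMSO. Of 12186 genes, 379 differed by more than 8-fold between DMSO and Ctrl, and 28 between shCtrl replicate 3 and Ctrl. The cells of the first and last experiments thus differed in expression well beyond the spread of replicates. CDKN2A, near absent in both, does not tell them apart. Whether they are the same line, and which of them is MDA-MB231, was not tested.

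**Figure D2:**
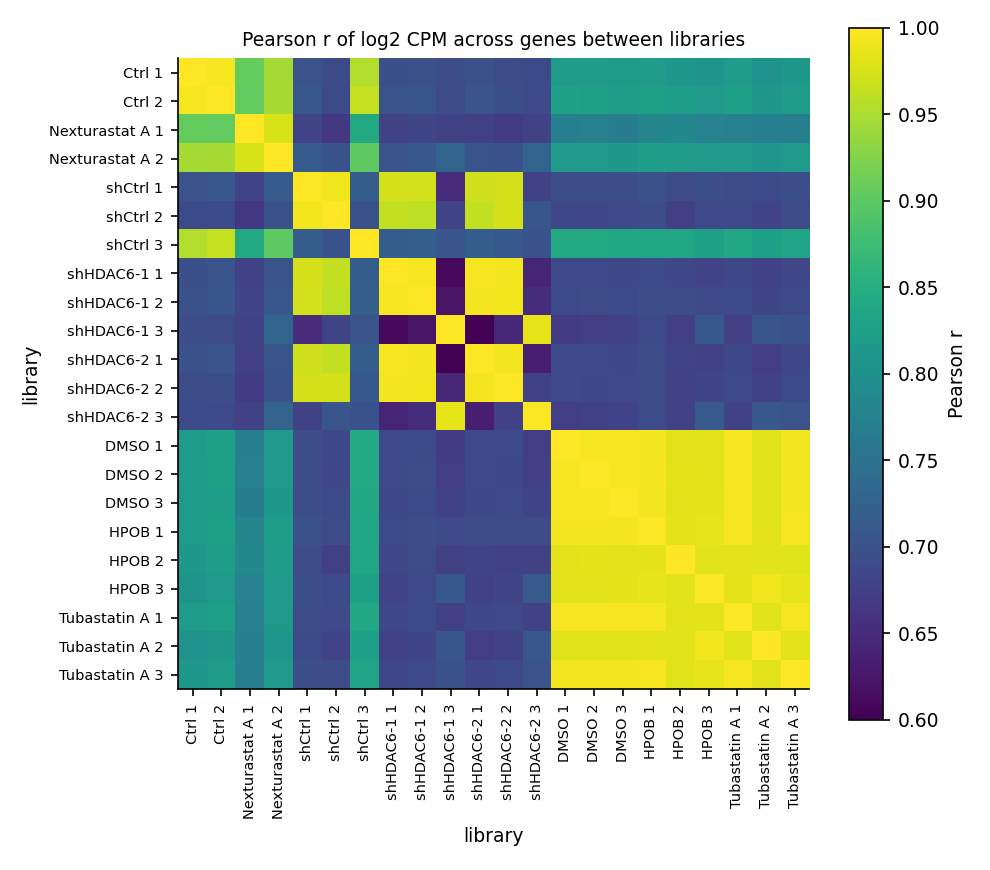
Pearson r of log2 CPM across genes for each pair of the 22 libraries (both axes list the libraries, colour gives r). Replicates 1 and 2 of the 3 knockdown groups form 1 block at 0.961 to 0.995 and lie at 0.689 to 0.708 against Ctrl.

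Nexturastat A against Ctrl asks what a hydroxamate inhibitor of HDAC6 does to gene expression in the cells of the first experiment, which stood apart from those of the last. DHRS2, a short-chain dehydrogenase gene known to be induced by histone deacetylase inhibitors, rose to 369 CPM ± 24.5 from 5.53 CPM ± 0.210 (SD, n = 2 each), a log2 fold change of 6.06 ± 0.15 (SE). The cell cycle inhibitor CDKN1A rose by 2.20 ± 0.16 and the growth factor AREG by 4.19 ± 0.50, while the airway mucin MUC5AC went from 209 CPM ± 61.4 to 2.00 CPM ± 1.98 (log2 fold change -6.70 ± 0.94). The chemokine CCL20 rose by 4.07 ± 0.32, and the DNA repair gene FANCD2 (-1.87 ± 0.41) and the desaturase SCD (-1.90 ± 0.14) fell. In all, 6112 of 16678 genes were called, 3520 higher and 2592 lower, and 2480 and 622 of these passed 2-fold. HDAC6 itself had a log2 fold change of -0.19 ± 0.14 (adjusted p = 0.328).

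Among the genes that rose most, at a mean log2 CPM of at least 2, were several near silent in Ctrl. ACTBL2, an actin-like gene on chromosome 5 from 57480016 to 57482809, had 42.1 CPM with Nexturastat A and a count ratio of 1240 (95% counting interval 484 to 4554). The ratio was 473 (184 to 1736) for the secreted ribonuclease RNASE1, 291 (190 to 470) for the cancer-testis gene SPANXB1, 141 (85.1 to 252) for the serpin SERPINB7 and 123 (70.4 to 239) for the class II antigen gene HLA-DPB1. FSTL5, DCAF8L1 and VWA5A were also among the 8 highest, with 1058 (293 to 8744), 238 (92.5 to 873) and 221 (101 to 602). The lowest, after MUC5AC on chromosome 11 from 1157953 to 1201138, were its neighbour MUC5B (-4.27 ± 0.49), SHISA3 (-3.17 ± 0.43), the anion transporter SLCO4A1 (-2.85 ± 0.16), the interferon-induced IFIT3 (-2.56 ± 0.49), the hyaluronan-binding CEMIP (-2.50 ± 0.16), SPOCD1 (-2.40 ± 0.38) and the transcription factor FOXQ1 (-2.37 ± 0.17). Of the other deacetylases, HDAC9 (1.63 ± 0.24), SIRT4 (1.73 ± 0.42), SIRT6 (0.56 ± 0.13) and SIRT7 (0.80 ± 0.13) rose, and HDAC1 (-0.49 ± 0.13), HDAC7 (-1.20 ± 0.18), HDAC8 (-0.51 ± 0.14) and SIRT1 (-0.77 ± 0.15) fell.

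Of 18 genes known to be induced by histone deacetylase inhibitors, 11 rose and 0 fell (14 and 0 when adjusted over the list alone), among them CPA4 (5.65 ± 0.41), MT1X (4.07 ± 0.68) and TUBB3 (2.15 ± 0.17). Camera gave the list an adjusted p = 3.88e-10 with the preset correlation and an adjusted p = 0.641 with an estimated correlation. Neuronal genes rose in 13 of 15 cases (14 adjusted over the list alone; adjusted p = 3.21e-07, and adjusted p = 0.641 with an estimated correlation). They include the vesicle protein SYT11, at a count ratio of 16.6 (10.8 to 26.8), and the adhesion molecule NCAM1, at 31.7 (12.1 to 118). NF-kB targets and inflammatory cytokines had 13 of 27 higher and 3 lower (14 and 3 adjusted over the list alone; adjusted p = 0.000951, and adjusted p = 0.641 with an estimated correlation). Among them were the chemokines CCL20 (4.07 ± 0.32) and CXCL8 (2.72 ± 0.20) and the apoptosis inhibitor BIRC3 (2.87 ± 0.26). Targets of NRF2, the regulator of the oxidative stress response, had 13 of 23 higher and 3 lower (15 and 4 adjusted over the list alone); the adjusted p = 0.000654, and the adjusted p = 0.641 with an estimated correlation. AKR1B10 (3.81 ± 0.22), SRXN1 (2.12 ± 0.21) and OSGIN1 (1.84 ± 0.24) led them. Glycolysis and hypoxia genes had 15 of 32 higher and 2 lower (18 and 3 adjusted over the list alone), with an adjusted p = 0.00182, and an adjusted p = 0.920 with an estimated correlation. Among them were ANGPTL4 (2.74 ± 0.18), EGLN3 (2.44 ± 0.28) and ADM (2.37 ± 0.24).

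Cohesin, condensin and CTCF genes, which shape chromatin loops, fell in 16 of 27 cases and rose in 0 (17 and 1 adjusted over the list alone). STAG2 (-1.22 ± 0.13), SMC1A (-1.22 ± 0.30) and NCAPD2 (-1.27 ± 0.31) were among them. The adjusted p = 7.48e-07, and the adjusted p = 0.878 with an estimated correlation. DNA repair genes fell in 15 of 32 cases (16 adjusted over the list alone), with FANCD2 (-1.87 ± 0.41), BRIP1 (-1.75 ± 0.47) and BRCA2 (-1.39 ± 0.41). The adjusted p = 2.19e-06, and the adjusted p = 0.878 with an estimated correlation. Polycomb and heterochromatin genes had 8 of 24 lower and 1 higher (the same counts adjusted over the list alone; adjusted p = 0.00217, and adjusted p = 0.878 with an estimated correlation). The heterochromatin protein CBX5 (-1.80 ± 0.17) and the methyltransferases SUV39H1 (-1.58 ± 0.33) and DNMT3A (-1.33 ± 0.17) fell. Fatty acid synthesis had 10 of 16 lower and 1 higher (11 and 2 adjusted over the list alone; adjusted p = 8.83e-05, and adjusted p = 0.641 with an estimated correlation). The desaturases SCD (-1.90 ± 0.14), FADS1 (-1.40 ± 0.16) and FADS2 (-1.36 ± 0.20) fell. Cholesterol synthesis had 10 of 23 lower and 2 higher (12 and 2 adjusted over the list alone; adjusted p = 0.00385, and adjusted p = 0.641 with an estimated correlation). IDI1, an isomerase of that pathway, fell (-0.93 ± 0.13). Interferon-stimulated genes had 15 of 37 lower and 2 higher (the same counts adjusted over the list alone; adjusted p = 0.000305, and adjusted p = 0.641 with an estimated correlation). UBA7 fell by 3.98 and BST2 rose by 2.67 on the log2 scale.

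Of the genes of mitosis and G2/M, 2 of 36 fell, namely ECT2 (-1.02 ± 0.19) and BUB3 (-0.62 ± 0.13), as did 2 adjusted over the list alone. In DNA replication and S phase 3 of 37 fell, namely PCNA (-0.97 ± 0.21), RFC4 (-0.95 ± 0.24) and POLA1 (-0.90 ± 0.25), and 0 adjusted over the list alone. The median log2 fold changes of these lists were -1.76 and -0.95, with an adjusted p = 4.55e-08 and an adjusted p = 8.83e-05. With an estimated correlation the adjusted p = 0.878 and the adjusted p = 0.920. Across all genes, Nexturastat A replicate 1 correlated with Ctrl at 0.904 to 0.906 and replicate 2 at 0.946 to 0.947.

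**Figure D3:**
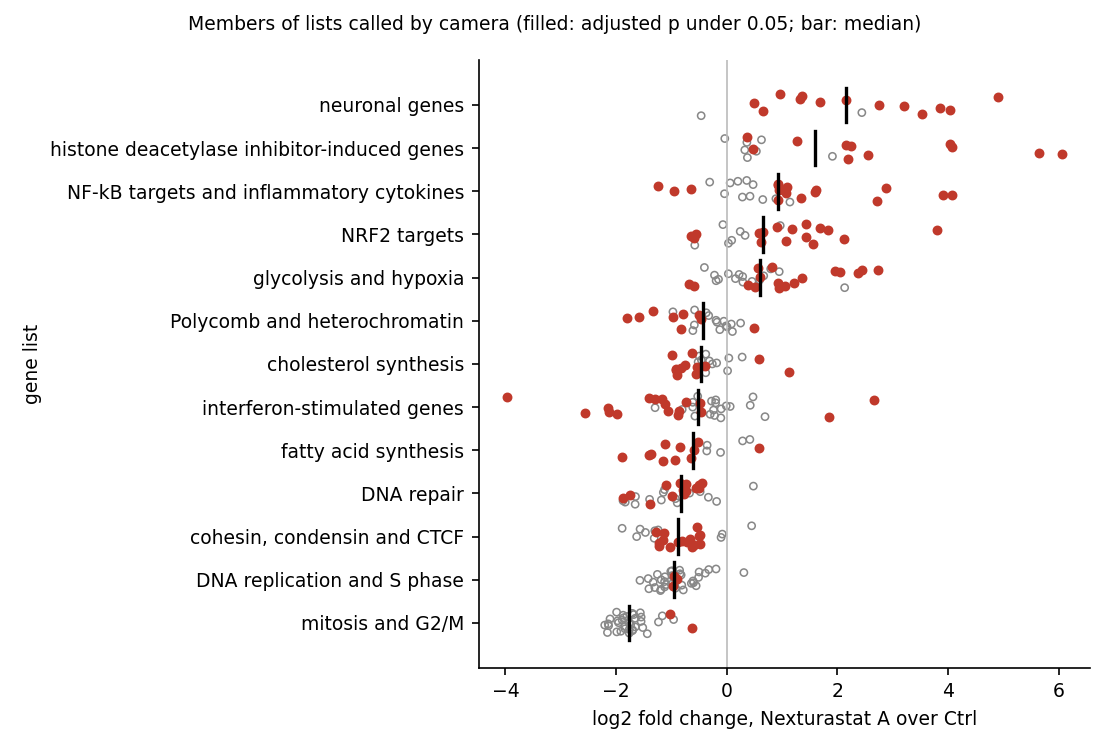
Log2 fold change of each measured member (horizontal axis) in 13 gene lists that camera called for Nexturastat A against Ctrl (vertical axis), with filled points for called genes and a bar at the median of the list. Medians run from -1.76 for mitosis and G2/M to 2.15 for neuronal genes.

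The count of called genes was 1781 without Ctrl replicate 1, 1921 without Ctrl replicate 2, 3586 among genes with a mean CPM of at least 5 and 11386 with the DMSO libraries as controls. With 2 libraries per group no permutation test could go under 0.05, and 33 of 127 calls were false in simulated data of this design. Only 200 of 16332 genes were changed in that simulation, so this share is no estimate for the real calls.

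The knockdown comparisons ask what loss of HDAC6 changes, with 2 hairpins as independent means to the same end. Over all 9 libraries HDAC6 had a log2 fold change of -1.79 (95% interval -2.62 to -0.95) with shHDAC6-1 and -1.64 (-2.47 to -0.81) with shHDAC6-2, yet neither it nor any other gene was called by edgeR. At an unadjusted p under 0.05 there were 191 and 219 genes, where 883 would be expected by chance. DESeq2 called 6 genes with each hairpin, 4 of them with both, and limma voom with library quality weights called 3492 and 2806, of which 2185 were called the same way with both. Between the hairpins edgeR called 0 genes (6 at an unadjusted p under 0.05), DESeq2 0 and voom 6. In simulated data of this design 0 of 200 changed genes were recovered, and adding replicate as a block left the counts at 0.

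Of the 34 lists, camera called 18 with shHDAC6-1, 16 with shHDAC6-2 and 3 between them over all 9 libraries, and 0 of these with an estimated correlation. Mitosis and G2/M genes had median log2 fold changes of -0.83 and -0.95 with the 2 hairpins (adjusted p = 1.57e-10 and adjusted p = 2.63e-12), with 0 of 36 members called, also when adjusted over the list alone. The adjusted p = 0.279 and the adjusted p = 0.387 with an estimated correlation. Within replicates 1 and 2 camera called this list with neither hairpin (adjusted p = 0.0528 with shHDAC6-2, and adjusted p = 0.0407 with the replicate block). The 9 libraries include replicate 3 of the hairpins, whose difference from shCtrl followed GC content (rank correlation across genes 0.812). ATF4 and amino acid response genes had medians of 0.48 and 0.59 (adjusted p = 8.13e-06 and adjusted p = 5.09e-11, and adjusted p = 0.241 and adjusted p = 0.209 with an estimated correlation), with 1 of 29 members higher adjusted over the list alone with each hairpin.

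Within replicates 1 and 2, taken alone after the data were seen, HDAC6 fell to 12.4 CPM ± 0.553 with shHDAC6-1 and 13.2 CPM ± 1.16 with shHDAC6-2 from 49.2 CPM ± 5.18 in shCtrl (SD, n = 2 each), on the scaling of the fit of these 6 libraries. These are log2 fold changes of -1.99 ± 0.14 (adjusted p = 9.52e-10) and -1.90 ± 0.14 (adjusted p = 1.77e-09). The zinc transporter SLC39A6 rose to 152 CPM ± 2.67 and 148 CPM ± 2.44 from 22.9 CPM ± 1.69, and CHAC1, which degrades glutathione and responds to ATF4, rose as well (log2 fold changes 2.36 ± 0.14 and 2.37 ± 0.14). The mitotic kinase AURKB fell to 47.3 CPM ± 3.46 and 46.5 CPM ± 2.04 from 169 CPM ± 12.6. The epoxidase SQLE of cholesterol synthesis rose (1.20 and 1.12) and the proapoptotic BAX fell (-1.06 and -1.11). All of these values come from the 6 libraries that correlated with Ctrl at 0.689 to 0.708 and that held CDKN2A mRNA at 132 CPM or more.

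Of 17702 genes, 5401 were called with shHDAC6-1 (2708 higher, 2693 lower) and 4880 with shHDAC6-2 (2544 higher, 2336 lower). Both hairpins shared 2009 higher and 1899 lower genes, and 0 genes went opposite ways. Independence would give 389 and 355, and simulated unchanged groups with the same controls shared at most 1. The simulations held no bias common to libraries. The real difference of the hairpins from shCtrl followed GC content (rank correlation across genes -0.384). Its medians ran from 0.18 in the fifth of genes with the lowest GC content to -0.23 in the highest. With GC and length trends removed 7380 and 7240 genes were called, 6015 of them the same way with both hairpins. The replicate block gave 6163 and 5685. The effects correlated across genes, which are not independent, at 0.786, against 0.495 in simulations of unchanged groups sharing controls. For shHDAC6-1 the count fell to 3563 without its replicate 1 and to 3160 without its replicate 2. Between the hairpins edgeR and DESeq2 called 0 genes, with 1107 at an unadjusted p under 0.05 in edgeR. Leaving out 1 library gave from 1 (without shHDAC6-1 replicate 2) to 66 (without shCtrl replicate 2). It gave 54 without shCtrl replicate 1, 25 without shHDAC6-1 replicate 1, 4 without shHDAC6-2 replicate 1 and 5 without shHDAC6-2 replicate 2.

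Among called genes with a mean log2 CPM of at least 2 and no overlap between groups, the highest log2 fold changes with shHDAC6-1 and shHDAC6-2 in turn were those of SLC39A6 (2.74 with shHDAC6-1; chromosome 18 from 36108532 to 36129385), the nuclear receptor NR6A1 (2.31 and 2.60), CWF19L1 (2.42 and 2.43), CHAC1 (2.36 and 2.37), ZHX1 (2.38 and 2.32) and GIPC3 (2.21 and 2.44). The kinesin KIF3B (2.35) and the fibrillin FBN2 (2.28) were among the 8 highest with shHDAC6-2, and the glycolipid transfer protein GLTP (2.26) and the pseudouridine synthase TRUB1 (2.16) with shHDAC6-1. The cancer-testis gene MAGEC1, on chromosome X from 141903894 to 141909388, was lowest among these (-3.63 and -3.67). Next came the phospholipase PLCD3 (-2.43 and -2.53), SPDYC (-2.42 and -2.58), the heat shock factor HSF4 (-2.43 and -2.20), MYO15B (-2.40 and -2.11), the melanosomal glycoprotein GPNMB (-2.39 and -2.22) and MYEOV (-2.13 and -2.41). The splicing protein SRRM2 (-2.27, shHDAC6-1) and the copine CPNE2 (-2.22, shHDAC6-2) completed the lowest 8. SIRT1 rose (0.75 and 0.59) and SIRT5 (-0.94 and -1.14) and SIRT6 (-0.50 and -0.46) fell. Over all 9 libraries SIRT1 (-0.17 and -0.34) and SIRT6 (0.67 and 0.45) had the opposite sign, as had MYEOV with shHDAC6-1 (0.73).

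**Figure D4:**
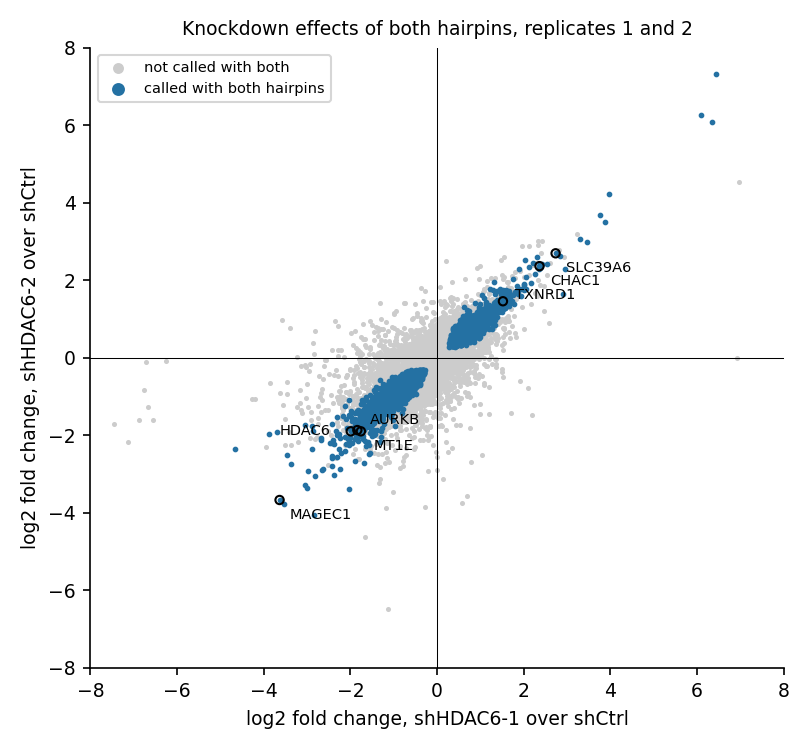
Log2 fold change of each gene with shHDAC6-1 (horizontal axis) and shHDAC6-2 (vertical axis) over shCtrl within replicates 1 and 2, with the 3908 genes called the same way with both hairpins in blue. HDAC6 lies at -1.99 and -1.90 and MAGEC1 at -3.63 and -3.67.

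In these 6 libraries, all of which hold CDKN2A and IRS4 mRNA, 17 of 29 ATF4 and amino acid response genes rose and 4 fell with shHDAC6-1 (18 and 5 adjusted over the list alone), and 15 rose and 3 fell with shHDAC6-2 (16 and 4). The cystine transporter SLC7A11 (1.10 and 1.14, but -0.077 with shHDAC6-1 over all 9 libraries) and the pseudokinase TRIB3 (0.96 and 0.89) were among them. The adjusted p = 3.58e-05 and the adjusted p = 9.63e-05, and with an estimated correlation the adjusted p = 0.423 and the adjusted p = 0.316. Endoplasmic reticulum chaperones had 13 of 22 higher with each hairpin and 3 and 2 lower (14 higher adjusted over the list alone), such as DNAJB9 (1.01 and 0.74). Camera gave an adjusted p = 0.000598 and an adjusted p = 0.000654. These were an adjusted p = 0.427 and an adjusted p = 0.316 with an estimated correlation. Proteasome genes rose in 16 and 12 of 31 cases and fell in 0 (18 and 15 adjusted over the list alone), with PSMB1 at 0.64 and 0.51. Here the adjusted p = 3.58e-05 and the adjusted p = 0.000736, against an adjusted p = 0.652 and an adjusted p = 0.629 with an estimated correlation. Cholesterol synthesis had 11 and 9 of 24 higher, 1 and 2 lower (11 and 9 higher, 2 and 2 lower adjusted over the list alone). The epoxidase SQLE (1.20 and 1.12) and the sterol sensor INSIG1 (1.21 and 1.06) rose. Its adjusted p = 0.00138 and its adjusted p = 0.00142. They were an adjusted p = 0.423 and an adjusted p = 0.316 with an estimated correlation. Autophagy and lysosome genes had 13 and 12 of 30 higher, 3 and 2 lower (14 and 13 higher, 4 and 2 lower adjusted over the list alone). Among them were the galactosidase GLA (0.96 and 0.79) and the proton pump subunit ATP6V1A (0.71 and 0.80). Their adjusted p = 0.00995 and adjusted p = 0.00796, and with an estimated correlation the adjusted p = 0.427 and the adjusted p = 0.316.

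Metallothioneins and zinc response genes fell in 5 and 6 of 7 cases (the same adjusted over the list alone), with MT1E at -1.76 and -1.90. The adjusted p = 0.00660 and the adjusted p = 0.000220, and with an estimated correlation the adjusted p = 0.436 and the adjusted p = 0.316. Interferon-stimulated genes fell in 15 and 14 of 39 cases and rose in 1 (15 and 15, and 1, adjusted over the list alone), with OAS2 at -1.46 and -1.98 and RSAD2 at -1.22 and -1.71. The adjusted p = 0.00601 and the adjusted p = 0.00142, and with an estimated correlation the adjusted p = 0.436 and the adjusted p = 0.316. With shHDAC6-1 alone camera also called nuclear oxidative phosphorylation genes (12 of 29 higher, 0 lower, 14 adjusted over the list alone; adjusted p = 0.00240, and adjusted p = 0.652 with an estimated correlation). It called cytosolic ribosomal proteins too (7 of 37 higher, 5 adjusted over the list alone; adjusted p = 0.00732, and adjusted p = 0.652 with an estimated correlation). With shHDAC6-2 alone it called basal breast cancer drivers and receptors (14 of 33 higher, 3 lower, 15 and 3 adjusted over the list alone; adjusted p = 0.0104, and adjusted p = 0.629 with an estimated correlation). Fatty acid synthesis was called as well (6 of 16 higher, 1 lower, the same adjusted over the list alone; adjusted p = 0.0392, and adjusted p = 0.344 with an estimated correlation). In all 9 libraries MT1E, OAS2 and RSAD2 went the other way with shHDAC6-1, at 0.18, 0.15 and 0.19.

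HPOB against DMSO asks whether a second hydroxamate inhibitor of HDAC6 moves the same genes. Inflammatory genes rose: CXCL8, a neutrophil chemokine on chromosome 4 from 73740506 to 73743716, went to 206 CPM ± 34.9 from 75.9 CPM ± 2.91 (SD, n = 3 each; log2 fold change 1.44 ± 0.16, adjusted p = 0.0109). The cytokine IL1A, on chromosome 2 from 112773915 to 112784590, went to 6.66 CPM ± 1.55 from 1.62 CPM ± 0.324 (2.04 ± 0.25, adjusted p = 0.0147). The cytokine IL24 went to 43.6 CPM ± 7.29 from 17.5 CPM ± 1.80 (1.32 ± 0.18, adjusted p = 0.0212), and TNFSF15, a ligand of the TNF family, to 40.0 CPM ± 1.86 from 23.6 CPM ± 1.22 (0.76 ± 0.10, adjusted p = 0.0147). Each was higher in 3 of 3 HPOB libraries than in any DMSO library. These 4 were the genes called of 15338, with 1588 at an unadjusted p under 0.05 where 767 would be expected by chance.

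**Figure D5:**
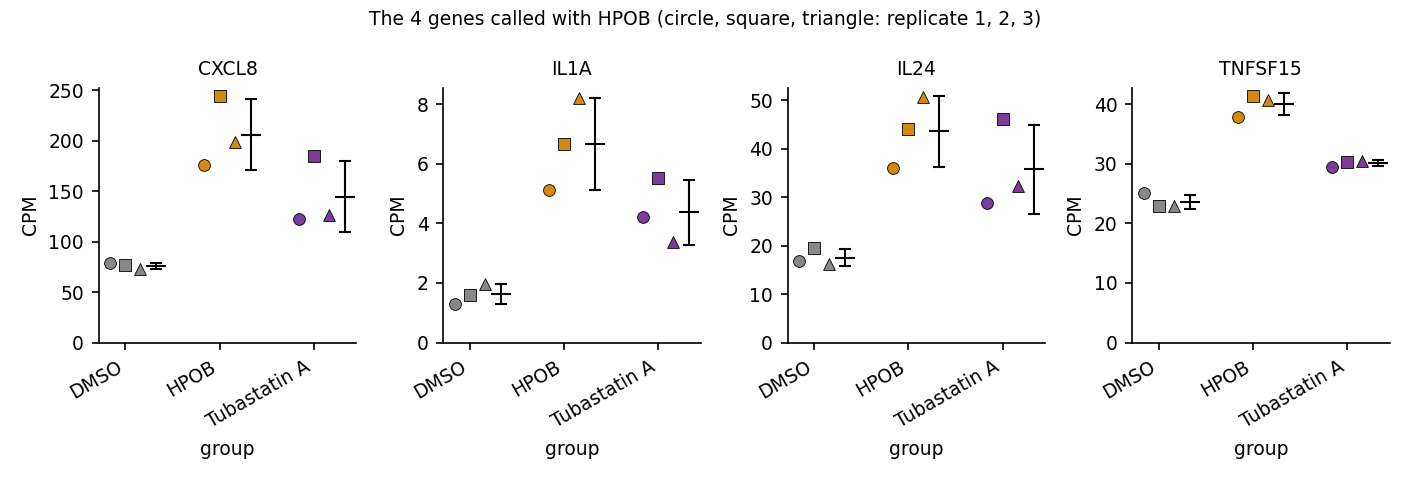
CPM (vertical axes) of the 4 genes called with HPOB in each library of the DMSO, HPOB and Tubastatin A groups (horizontal axes), with the mean and SD of the group beside the points. CXCL8 lies at 176 to 244 CPM with HPOB, 123 to 185 CPM with Tubastatin A and 72.8 to 78.5 CPM in DMSO.

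Of 34 lists camera called 23 with HPOB, 16 up and 7 down, and 0 with an estimated correlation. NF-kB targets and inflammatory cytokines led, with 2 of 29 members called over all genes, IL1A and CXCL8, and 17 higher and 0 lower adjusted over the list alone (adjusted p = 2.03e-25, and adjusted p = 0.0854 with an estimated correlation). AP-1 and MAPK output had 8 of 29 higher adjusted over the list alone and 0 over all genes (adjusted p = 1.72e-05, and adjusted p = 0.0854 with an estimated correlation). Endoplasmic reticulum chaperones had 7 of 22 higher adjusted over the list alone and 0 over all genes (adjusted p = 3.59e-07, and adjusted p = 0.117 with an estimated correlation). Genes known to be induced by histone deacetylase inhibitors had 4 of 18 higher adjusted over the list alone, 0 over all genes and a median log2 fold change of 0.26 (adjusted p = 1.81e-05, and adjusted p = 0.230 with an estimated correlation). Cytosolic ribosomal proteins had a median of 0.26 with 0 of 37 called, also over the list alone (adjusted p = 5.68e-08, and adjusted p = 0.425 with an estimated correlation). DNA repair genes had a median of -0.18 with 0 of 32 called (adjusted p = 5.32e-05, and adjusted p = 0.226 with an estimated correlation). As a set, HPOB replicates 2 and 3 and Tubastatin A replicate 2 differed from the other treated libraries with transcript length, by pooled medians from 0.24 in the fifth of genes with the shortest transcripts to -0.26 in that with the longest.

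The number of calls depended on single libraries, although each HPOB library stood above each DMSO library at the 4 genes. Leaving out DMSO replicate 1, 2 or 3 or HPOB replicate 2 gave 0 calls. Leaving out HPOB replicate 3 gave 1, and leaving out Tubastatin A replicate 2 gave 78. DESeq2 called 120 genes, limma voom 51, a fit of the 2 groups alone 15, the fit without a filter on low counts 14, that with the replicate block 7 and that at a mean CPM of at least 5 gave 2.

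Tubastatin A against DMSO asks the same of another hydroxamate inhibitor. The genes called with HPOB had log2 fold changes above 0 here too, 1.43 for IL1A (95% interval 0.88 to 1.98), 1.03 for IL24 (0.65 to 1.41), 0.93 for CXCL8 (0.59 to 1.27) and 0.35 for TNFSF15 (0.14 to 0.56), but none passed the test (adjusted p = 0.446 for the first 3 and adjusted p = 0.857 for TNFSF15). They were picked as high against these same DMSO libraries, which favours values above 0 here. In simulated unchanged groups that share the DMSO libraries, 66.6% of genes had the same sign with both compounds. In CPM, CXCL8 stood at 145 ± 35.0 and IL1A at 4.37 ± 1.09 (SD, n = 3). Of 15338 genes, edgeR called 0, with 757 at an unadjusted p under 0.05, while DESeq2 called 23, voom 21 and the fit with GC and length trends removed 3. Camera called 12 lists, 8 up and 4 down, and 0 with an estimated correlation.

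NF-kB targets and inflammatory cytokines had 14 of 29 members higher adjusted over the list alone and 0 over all genes with Tubastatin A (adjusted p = 1.25e-19, and adjusted p = 0.111 with an estimated correlation). ATF4 and amino acid response genes had 3 of 29 higher adjusted over the list alone and 0 over all genes (adjusted p = 6.48e-07, and adjusted p = 0.119 with an estimated correlation). AP-1 and MAPK output had 6 of 29 and endoplasmic reticulum chaperones 3 of 22 higher adjusted over the list alone, and 0 over all genes (adjusted p = 6.56e-06 and adjusted p = 2.69e-06, and adjusted p = 0.0863 and adjusted p = 0.111 with an estimated correlation). Mitosis and G2/M genes had a median log2 fold change of -0.13 and S phase genes of -0.09, with 0 members called on either basis (adjusted p = 1.62e-06 and adjusted p = 1.38e-05, and adjusted p = 0.111 and adjusted p = 0.0863 with an estimated correlation). Tubastatin A replicate 2 stood apart in these data, with a mean correlation with DMSO of 0.979 against 0.995 and 0.994 for replicates 1 and 3, and the mitotic gene MKI67 was lower in the set of 3 libraries that holds it (log2 difference of the other 3 from these 0.86).

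HPOB, Tubastatin A and Nexturastat A all carry a hydroxamate on a benzene ring. They differ in the cap group, an N-hydroxyethyl anilide in HPOB, a tetrahydro-gamma-carboline in Tubastatin A and a butyl phenyl urea in Nexturastat A. Between Tubastatin A and HPOB edgeR called 0 genes (481 at an unadjusted p under 0.05; DESeq2 0, voom 0), at doses not given in the sources used here. The difference, Tubastatin A minus HPOB, was -0.61 for IL1A (95% interval -1.12 to -0.10), -0.51 for CXCL8 (-0.85 to -0.17), -0.41 for TNFSF15 (-0.61 to -0.20) and -0.29 for IL24 (-0.66 to 0.09), with an adjusted p = 0.996 for each. These genes were picked for their rise with HPOB, which favours values below 0 here. Camera called 6 lists, 0 with an estimated correlation. NF-kB targets and inflammatory cytokines had a median of -0.13 with 0 of 29 called (adjusted p = 0.000382, and adjusted p = 0.817 with an estimated correlation). Cytosolic ribosomal proteins had a median of -0.12 with 0 of 37 called (adjusted p = 0.000101, and adjusted p = 0.817 with an estimated correlation). The effects of both compounds correlated across genes, which are not independent, at 0.607, against 0.502 in simulated unchanged groups that share the DMSO libraries. The simulations held no deviation common to libraries, whereas residuals of HPOB replicate 3 and Tubastatin A replicate 2 correlated across genes at 0.458. The gap therefore cannot tell a shared effect of the compounds from a shared deviation of libraries.

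The effect of Nexturastat A was then set against those of HPOB and Tubastatin A, although the experiments and controls differed and the doses of both latter compounds are not given in the sources used here. ACTBL2, HLA-DRA and FSTL5 were among the 4 highest differences from both, and MUC5AC (-5.99 from HPOB, -6.61 from Tubastatin A) and the interferon-stimulated gene UBA7 (-4.08 and -4.12) among the 4 lowest. Besides these, the kinase gene ALPK2 was among the highest and the fatty acid-binding FABP4 (-4.63) and the sodium channel SCN2A (-3.68) among the lowest from HPOB. From Tubastatin A these were the inflammasome gene NLRP2, and SFTA3 (-3.75) and the stress protein NUPR1, at 0.211 CPM with Nexturastat A against 2.09 CPM in Ctrl. On a scaling of all libraries, FABP4 stood at 0 to 0.0543 CPM in DMSO and 0.127 to 0.626 CPM with HPOB. It stood at 24.4 and 57.7 CPM with Nexturastat A and at 43.9 and 59.8 CPM in Ctrl. Its difference from HPOB thus rests on libraries with few counts and is no exact measure. HDAC7 (-1.09 and -1.28) fell further and HDAC9 (1.56 and 1.58) and SIRT7 (0.69 and 0.60) rose further with Nexturastat A. CXCL8 rose further by 1.33 (adjusted p = 0.00332) and 1.85 (adjusted p = 0.000262) and TNFSF15 by 1.39 (adjusted p = 0.000115) and 1.81 (adjusted p = 8.91e-06), while IL1A differed by -0.64 (95% interval -1.50 to 0.21, adjusted p = 0.297) and -0.02 (-0.91 to 0.86, adjusted p = 0.996).

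The joint fit estimates the spread of a gene over all 13 libraries. Pairs of DMSO replicates varied less (chi-square per degree of freedom 4.42 to 5.47) than the Nexturastat A pair (114). Calls of this fit may therefore understate the spread between the Nexturastat A libraries. Mitosis and G2/M genes fell further with Nexturastat A in 31 of 36 cases from each compound (35 adjusted over the list alone), although most were not called in the fit of the first experiment alone. The adjusted p = 7.69e-20 and the adjusted p = 8.13e-18, and with an estimated correlation an adjusted p = 0.363 and an adjusted p = 0.386. Cohesin, condensin and CTCF genes did so in 11 and 12 of 27 cases (17 adjusted over the list alone, with 1 higher; adjusted p = 1.34e-06 and adjusted p = 7.35e-07), and with an estimated correlation the adjusted p = 0.363 and the adjusted p = 0.386. Genes induced by histone deacetylase inhibitors rose further in 9 and 10 of 18 cases (11 adjusted over the list alone; adjusted p = 7.51e-10 and adjusted p = 5.52e-10, and adjusted p = 0.167 and adjusted p = 0.125 with an estimated correlation). Markers of endothelial cells had 3 of 7 higher from HPOB (the same adjusted over the list alone; adjusted p = 0.0309, and adjusted p = 0.101 with an estimated correlation). In all, 2990 of 17083 genes were called from HPOB (1676 higher, 1314 lower) and 3258 from Tubastatin A (1813 higher, 1445 lower). These counts were 1751 and 1891 without Ctrl replicate 1, 1603 and 1857 without Ctrl replicate 2, and 1826 and 2000 without Nexturastat A replicate 1.

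Across experiments, CXCL8, IL1A, IL24 and TNFSF15, the 4 genes called with HPOB, were all called higher with Nexturastat A, where 0.675 would be expected of 14748 genes (Fisher's exact test across genes, which are not independent, one-sided p = 0.000808). There CXCL8 stood at 262 CPM ± 63.7, against 39.7 CPM ± 5.86 in Ctrl (SD, n = 2), IL1A had a log2 fold change of 1.35 ± 0.31 and TNFSF15 of 2.10 ± 0.26, and IL24, with no counts in Ctrl, was at least 40.0-fold higher. With the DMSO libraries as controls for Nexturastat A, 2 of the 4 turned, IL24 to -4.12 and TNFSF15 to -2.13. In replicates 1 and 2 of the knockdown experiment, 3 of the 4 were tested. IL1A was called higher with both hairpins, at count ratios of 15.2 (8.44 to 29.99) and 11.7 (6.47 to 23.1), as was CXCL8 (1.26 ± 0.17 and 0.77 ± 0.17), whereas TNFSF15 had 0.16 ± 0.26 (adjusted p = 0.685) and 0.30 ± 0.26 (adjusted p = 0.410). Nexturastat A and the hairpins called more genes in opposite directions there than independence would give. With shHDAC6-1, 632 were higher with Nexturastat A and lower with the hairpin (473 expected), and 564 the other way (426 expected). With shHDAC6-2 these were 559 (412 expected) and 555 (399 expected). Genes called in the same direction did not exceed independence, at 328 higher and 382 lower with shHDAC6-1 (500 and 403 expected). Replicates 1 and 2 hold CDKN2A mRNA and may not be MDA-MB231 cells, and their hairpin difference followed GC content (rank correlation across genes -0.384). Whether the opposite directions come from HDAC6 was not tested. At a minimum of 1.5-fold, genes higher with Nexturastat A and lower with the hairpins numbered 434 (260 expected) and 386 (229 expected), and the other way 141 (135 expected) and 138 (127 expected). The effects correlated across genes at -0.141 and -0.157 within replicates 1 and 2, but at 0.0620 and 0.0597 over all 9 libraries. The effect of Nexturastat A correlated across genes with that of HPOB at 0.25 and with that of Tubastatin A at 0.18, and 71.9% and 66.8% of the genes called with Nexturastat A had the same sign there.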

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

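All tests of explanations in this part were chosen only after the result was seen, except the test of HDAC6 loss against replicate 3 of the hairpins and the counts of splits, which were planned. The effect of Nexturastat A differed from that of HPOB at 2990 of 17083 genes by the interaction term, MUC5AC and UBA7 among the lowest. The effect of Nexturastat A differed from that of Tubastatin A at 3258 genes by the same test, again with MUC5AC and UBA7 among the lowest. These differences between compounds cannot be separated from dose, which is not given for HPOB and Tubastatin A, or from experiment. DMSO correlated with Ctrl across genes at only 0.819 to 0.828, and 379 of 12186 genes differed by more than 8-fold between these controls. CD74 stood at no more than 0.0644 CPM in Ctrl and at 149 CPM or more in DMSO. NKX2-1 stood at 51.96 CPM or more in Ctrl and at no more than 1.55 CPM in DMSO. The cells of these experiments thus differed in expression too. Whether they are the same line was not tested, and effects of the compounds may differ with the cells.

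Replicates 1 and 2 of the knockdown experiment, shCtrl included, stand apart from all other libraries. They hold mRNA of CDKN2A and its neighbour MTAP (29.4 to 41.4 CPM), both lost from MDA-MB231 cells, and of IRS4, IGF2BP1 and LIN28B (73.6 to 139 CPM). Loss of HDAC6 is argued against, since shCtrl replicates 1 and 2 themselves correlate with Ctrl at 0.700, as is bias with GC content or length, since removing these trends leaves 0.716. Of 8 markers of HEK293-like embryonic kidney cells written down before the test, 4 (LIN28B, PAX2, IGF2BP1 and HOXD10) had a lowest CPM in the 6 libraries at least 10 times the highest in the 13 libraries of the compounds and their controls. CDKN2A stood at 132.5 to 175.1 CPM in the 6 libraries, while the 13 others held at most 0.0320 CPM of CDKN2A and 0.0322 CPM of MTAP. As both genes are lost from MDA-MB231 cells, these values argue against those cells as the only source of this RNA. RNA of another, HEK293-like cell type is therefore a candidate explanation, and the effects of the hairpins within these replicates may not be those of MDA-MB231 cells.

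Replicate 3 of both hairpins differs from replicate 3 of shCtrl by more than 8-fold at 1307 genes of 11650, of which 1081 were lower. The difference follows GC content (rank correlation across genes 0.812), with medians from -2.54 in the fifth of genes with the lowest GC content to 1.31 in the highest, and 13.9% of the genes stay over 8-fold apart once GC and length trends are removed. A GC or length bias of these libraries is therefore a candidate cause of most of it. Loss of HDAC6 stays open. The planned test, the correlation across genes with the difference within replicates 1 and 2, gave -0.291, and -0.036 once the trends are removed. It cannot decide, since those replicates may hold RNA of another cell type. The raw differences also followed GC content in opposite directions (0.812 and -0.384). RNA of the cells of replicates 1 and 2 cannot explain the 1081 lower genes, but might explain those near absent in shCtrl replicate 3, such as CDKN2A at 8.83 and 29.05 CPM: with the trends removed 4.35% of 23 such genes (1 gene) fell below 0.1 of the median ratio in each library, and 3 genes did before.

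HPOB replicates 2 and 3 and Tubastatin A replicate 2 stand apart from the other libraries of their experiment: their mean correlations with DMSO are 0.983, 0.982 and 0.979, while HPOB replicate 1 and Tubastatin A replicates 1 and 3, 3 treated libraries, reach 0.994, 0.995 and 0.994. This restates the pattern, so an effect of the compounds as labelled stays open. The trends with GC content and longest transcript length, as fitted here, are not the whole cause. After their removal 1605 genes were called between these sets of treated libraries, against 2984 before. The fitted trends took up 39.7% of the variance of the difference, so a technical bias that they miss stays open. Swapped labels of HPOB replicate 1 and Tubastatin A replicate 2 stay open. With the labels exchanged 2984 genes were called between the compounds and 3429 for HPOB against DMSO. A technical difference between the same sets of libraries could give such counts too. Values go both ways: TNFSF15 runs as labelled (37.9 CPM in HPOB replicate 1, 30.4 CPM in Tubastatin A replicate 2), as does the correlation of HPOB replicate 2 with these libraries (0.984 and 0.981), while CXCL8 (176 and 185 CPM), IL1A (5.12 and 5.52 CPM), IL24 (36.1 and 46.2 CPM) and the correlation of HPOB replicate 3 with them (0.986 and 0.993) run as an exchange would. The genes named were called for HPOB under the labels as given, which favours values as labelled, so TNFSF15 is no evidence against an exchange.

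Splits of 3 libraries against 3 number 10, too few for a share under 0.05. For HPOB against DMSO the real split gave 4 genes and the highest other 0, so 1 split gave as many. For each hairpin against shCtrl, between the hairpins, and for Tubastatin A against DMSO, the real split gave 0 genes and the highest other 0, so all 10 gave as many. For Tubastatin A against HPOB the real split gave 0 and the highest other 2984, again 10 splits of 10, which points to a structure of the samples. That split is the one given by the exchange of labels above.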

How the results depend on the processing

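Alternatives chosen only after the data were seen were replicates 1 and 2 alone, limma voom, removal of GC and length trends, and leaving out HPOB replicate 3 with Tubastatin A replicate 2. Of 3000 values of 223 named genes under the alternatives, 2674 kept their direction and side of the threshold, 274 lost the call, 22 gained it and 30 reversed. For the changes below the cause was not tested, unless stated.

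With Nexturastat A 3586 genes were called at a mean CPM of at least 5, where fewer genes are tested, 11386 with the DMSO libraries as controls, and 1781 to 8922 with 1 library left out, the lowest without Ctrl replicate 1. A lone library was assumed to vary like the other group. With 1 library left out the interaction counts ran from 1603 to 3950 (HPOB) and from 1857 to 4262 (Tubastatin A), the lowest without Ctrl replicate 2. With trends removed they were 4059 and 4329, and by voom 3510 and 4681. With the DMSO libraries as controls, which come from another experiment, these genes reversed: HDAC1 0.089, HDAC9 -1.69, SIRT7 -0.068, SPANXB1 -1.74, SHISA3 4.68, CPA4 -1.79, DNMT3A 0.91, BST2 -2.75, PMVK -0.73, IL24 -4.12 and TNFSF15 -2.13. Without a filter on low counts the median log2 fold change of all genes went from 0.033 to 0.15.

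For the knockdown, edgeR gave 0 calls over 9 libraries (191 and 219 at an unadjusted p under 0.05), DESeq2 6 and 6 (4 with both) and voom 3492 and 2806 (2185 with both), with 6 between the hairpins. Replicates 1 and 2 alone gave 5401 and 4880 (3908 with both), 7380 and 7240 with trends removed (6015), 5552 and 5040 by DESeq2 (4085), 6163 and 5685 with the replicate block (4607), and 5505 and 4926 with DESeq2 size factors (3969). With them, 842 genes called with Nexturastat A were called the same way with HPOB, Tubastatin A or either hairpin, against 4 with all 9 libraries, where the hairpins add none. This is no excess of agreement. With shHDAC6-1, 328 genes were higher and 382 lower in both, where independence would give 500 and 403. With shHDAC6-2 there were 311 and 314, where it would give 468 and 351. Over all 9 libraries these genes had the opposite sign, with shHDAC6-1: HDAC5 0.38, SIRT1 -0.17, SIRT2 0.19, SIRT6 0.67, MYEOV 0.73, MT1E 0.18, MT1X 0.84, PSMA4 -0.20, SLC7A11 -0.077, OAS2 0.15, OAS1 0.81 and RSAD2 0.19. With shHDAC6-2 these were SIRT1 -0.34, SIRT6 0.45, MT1A 1.25, MT1E 0.0092, PSMD1 -0.24, MX2 0.64 and PIK3CB -0.086.

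For HPOB, where CXCL8, IL1A, IL24 and TNFSF15 were called, the count was 14 without a filter, 2 at a mean CPM of at least 5, 120 by DESeq2, 7 with the block, 15 with 2 groups alone, 51 by voom, 15 with trends removed, 20 without HPOB replicate 3 and Tubastatin A replicate 2, and 0 to 78 with 1 library left out. It was 0 without DMSO replicate 1, 2 or 3 or HPOB replicate 2, 1 without HPOB replicate 3 and 78 without Tubastatin A replicate 2. For Tubastatin A it was 23 by DESeq2, 3 with trends removed and 21 by voom. Of 119 list tests that camera called, 0 were called with an estimated correlation. At a depth of 31.2 to 41.3 M counts the compound design recovered 37.3% of simulated 1.5-fold changes.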

Other observations

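The genes named here for Nexturastat A belong to lists that camera did not call as a whole, and no test in this part was chosen after a result was seen. Members of these lists went both ways: 5 of 17 genes of the BCL2 family rose and 2 fell, as did 4 and 3 of 26 heat shock and aggresome genes and 8 and 7 of 25 targets of YAP and TEAD. The proapoptotic BMF rose by 2.73 ± 0.32 (log2, SE), to 9.59 CPM from 1.44 CPM, and the antiapoptotic BCL2L1 by 0.96 ± 0.14, to 623 CPM from 320 CPM. The autophagy receptor SQSTM1, which binds ubiquitinated cargo, rose by 1.23 ± 0.14 to 1198 CPM ± 106 (SD, n = 2), and the chaperone HSPB8 by 3.35 ± 0.21. The cytokine GDF15 rose by 2.63 ± 0.14 and the oncogene MYC by 2.05 ± 0.14. ANKRD1, a target of YAP, reached 1434 CPM ± 198 from 214 CPM ± 37.1, and tissue factor F3 rose by 1.85 ± 0.15.

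Of adhesion, integrin and matrix protease genes 11 of 35 rose and 6 fell, of epithelial markers 9 of 28 and 4, of mesenchymal markers 8 of 23 and 4, and of histone genes 8 of 18 and 1. The collagenase MMP13 rose by 4.19 ± 0.34, the collagen COL1A1 by 1.84 ± 0.19 and the tight junction genes TJP3 and CLDN1 by 2.62 ± 0.19 and 2.22 ± 0.16. The linker histone HIST1H1C rose by 2.45 ± 0.53 and the core histone HIST1H2BD by 3.66 ± 0.60. Of genes of tubulins and microtubule acetylation, closest to the substrate of HDAC6, 4 of 22 rose and 1 fell (the same adjusted over the list alone). TUBB4A rose by 1.47 ± 0.19 and the microtubule destabiliser STMN1 fell to 170 CPM ± 28.5 from 376 CPM ± 31.0 (-1.15 ± 0.16). The list had a median of -0.23 and an adjusted p = 0.790.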
